A study of Drosophila melanogaster with 37 samples.

How the data were processed

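The series holds 37 mNET-seq samples of total, serine 2 phosphorylated and serine 5 phosphorylated Pol II from male and female stage 15 embryos of control and mof RNAi mothers. Samples were grouped by antibody, sex and RNAi from their titles, into 12 groups of 2 to 4. Per the submitters' processing notes, cutadapt 2.8, STAR 2.7.4a, SAMtools 1.20, DESeq and DESeq2 were used by the submitters, with build dm6. The role and settings of each are not given in the sources used here. Per-sample coverage was not analysed here, so no comparison of mof knockdown with control, of males with females or of Pol II forms was tested, and no depth per sample can be given. No statement about transcription levels follows from the values given.

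The deposited annotation was in GFF version 2, written with rtracklayer 1.48.0 per the file headers, and gave for each TU its arm, start, end, strand, length, gene symbols and FlyBase gene and transcript identifiers. Coordinates are 1-based. Its header and labels do not say how genes were merged. The length attribute equalled end minus start plus 1 in all 15991 TUs, 0 TUs overlapped another on the same strand, and 0 genes were assigned to more than 1 TU. Gene classes came from a RefSeq gene table of the same assembly, matched by symbol or by a synonym that fitted 1 gene on that chromosome, which found 17626 of 17698 genes and left 72 without a class. TUs of unmatched genes alone, 3 on the X and 22 on the autosome arms, were counted as having no protein-coding gene. Of 14821 single-gene TUs matched to RefSeq, 14709 (99.2%) had the same start and end as the RefSeq gene, and 1089 of 1098 merged TUs with matched members (99.2%) equalled the union of overlapping RefSeq genes. TU starts are therefore the outermost annotated starts of genes, not starts measured in these embryos, and a gene with several promoters has 1 start here.

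The X was compared with 2L, 2R, 3L and 3R pooled. Chromosome 4 was kept out of the main comparisons, was added to the autosomes as an alternative, and was tested against the 4 autosome arms after the data were seen. The Y is given as values only. Density was the number of TUs divided by the end of the last TU of the arm. The gap was the distance in bp to the nearest TU on either strand, with 0 for overlap, and overlap needed 1 bp. A divergent start was an opposite-strand TU start 0 to 500 bp upstream. An isolated TU had at least 2000 bp and no other TU within 500 bp of either end, but could contain a smaller TU. Differences of medians were tested by two-sided permutation of the X label over TUs with 100000 resamples, and shares by Fisher's exact test, two-sided. Odds ratios carry 95% confidence intervals. A divergent start or an opposite-strand overlap is counted for both TUs of a pair, while Fisher's test and the intervals take TUs as independent. The 7 X against autosome comparisons were adjusted together by the Benjamini-Hochberg method, as were 55 tests of 11 gene lists (5 features each) against the other TUs with a protein-coding gene on the 5 arms. The threshold was 0.05. Lists of under 10 genes have too many possible draws to enumerate for length, so these permutation tests also used 100000 resamples.

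The tests of the X against the autosomes, the gene lists and the rule for named genes were fixed before the data were examined. The rule named each MSL complex and roX gene, the first 4 genes of each other list, and the 3 longest TUs on the X and on the autosome arms. The comparisons of merged TUs and non-coding TUs and the tests of the lists were added after seeing the data. Alternatives left out each autosome arm, added chromosome 4, kept TUs of at least 1000 bp, or changed distances and overlap minimums. Alternatives added later kept TUs with a protein-coding gene or, for length, protein-coding TUs of 1 gene. Others barred any overlap from isolated TUs, or permuted the X label over 1 Mb blocks, which allows for neighbouring TUs being alike.

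The permutation test was tested on simulated data: with shuffled labels over 15739 TUs it called 6% of 100 simulations of the length comparison, and it called 90% with X lengths multiplied by 1.1 and 100% with 1.2. Fisher's exact test of the divergent share called 5.8% of 500 simulations without a difference, 53.6% with a share 2 points lower on the X and 99.4% with 4 points. The length simulations used 500 resamples each. Both sets of simulations took TUs as independent, so they do not cover pairs of TUs or the likeness of neighbouring TUs. Neighbour distances were checked against plain loops on simulated TUs. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Comparisons of GC content, GA repeats and core promoter motifs, which need the genome sequence, were not run.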

Results

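The series profiled RNA polymerase II (Pol II) in stage 15 Drosophila melanogaster embryos by mNET-seq, which sequences the nascent RNA held by immunoprecipitated polymerase. Polymerase was captured as total Pol II or by phosphorylation of its C-terminal domain (CTD) at serine 2 or serine 5. Embryos were sexed, and their mothers carried either a control RNAi or an RNAi against mof, which encodes the histone H4 lysine 16 acetyltransferase of the male-specific lethal (MSL) dosage compensation complex. The 37 samples fell into 12 groups of 2 to 4 samples. There were 14 total Pol II samples (4 female control, 4 female mof knockdown, 3 male control and 3 male mof knockdown). There were 15 serine 5 samples (3 female control, 4 in each of the other groups) and 8 serine 2 samples (2 in each group). Each preparation started from 6000 embryos. Coverage values of these samples were not analysed here, so the effect of the knockdown, the difference between the sexes and the level of mof itself carry no value, and the sequencing depth is unknown.

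The material analysed was the transcription unit (TU) annotation of the study, in build dm6. A TU is a stranded interval that holds 1 gene or several genes. The title of the series concerns dosage compensation, in which X-linked transcription is raised in males, so each property of the TUs was compared between the X and the 4 large autosome arms, 2L, 2R, 3L and 3R. These properties describe the intervals over which polymerase signal can be summed and the neighbours that lie close to them. The annotation listed 15991 TUs, 7996 on the plus and 7995 on the minus strand, which held 17698 genes and 34736 transcripts. TUs of a genome are a census and are not biological replicates, so the tests below describe how labels were distributed over TUs.

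The MSL complex and its roX RNAs were present in full, with 8 of 8 members in the annotation and 3 of them on the X. mof (FBgn0014340), the target of the knockdown, was the single gene of a TU of 3014 bp on the X, minus strand, from 5873840 to 5876853. Usp30, on the same strand, was its nearest neighbour at 146 bp, and no TU overlapped mof on the opposite strand. The non-coding RNA roX1 (FBgn0019661) spanned 5468 bp on the X from 3857230 to 3862697, minus strand, and its 3' end was overlapped by the plus-strand TU of ec, which ended at 3857621 and also held 2 tRNA genes and CG2901. roX2 (FBgn0019660), the other non-coding RNA of the complex, spanned 1368 bp on the X from 11579065 to 11580432, plus strand, 258 bp from its nearest neighbour and with no overlap.

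The 4 other protein subunits of the complex lay on autosomes. msl-2 (FBgn0005616), whose product is limited to males, occupied 2L from 3462218 to 3466112, minus strand, in a TU of 3895 bp that also held mir-4971, and its start faced that of ND-PDSW at 45 bp. msl-1 (FBgn0005617) spanned 5081 bp on 2L from 18683720 to 18688800, minus strand, and its nearest TU lay 4 bp away. msl-3 (FBgn0002775) spanned 2321 bp on 3L from 7123213 to 7125533, minus strand, was overlapped on the opposite strand by form3 and had a divergent start with BBS1 at 372 bp. The helicase gene mle (FBgn0002774) spanned 5922 bp on 2R from 5974857 to 5980778, minus strand, 471 bp from its nearest neighbour. Clamp (FBgn0032979), a GA-repeat binding protein that helps recruit the complex, spanned 3424 bp on 2L from 22165720 to 22169143, minus strand, and was overlapped by a TU of CR43241, CG42748 and dunk. Of the 8 members, 3 overlapped a TU on the opposite strand, 2 had a divergent start and 0 were isolated. The shares of the other TUs with a protein-coding gene were 39.8%, 27.3% and 10.4%, and none of these shares passed Fisher's exact test (p = 1 for each, two-sided). With 8 genes, a count of 0 isolated TUs could not have passed.

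**Figure D1:**
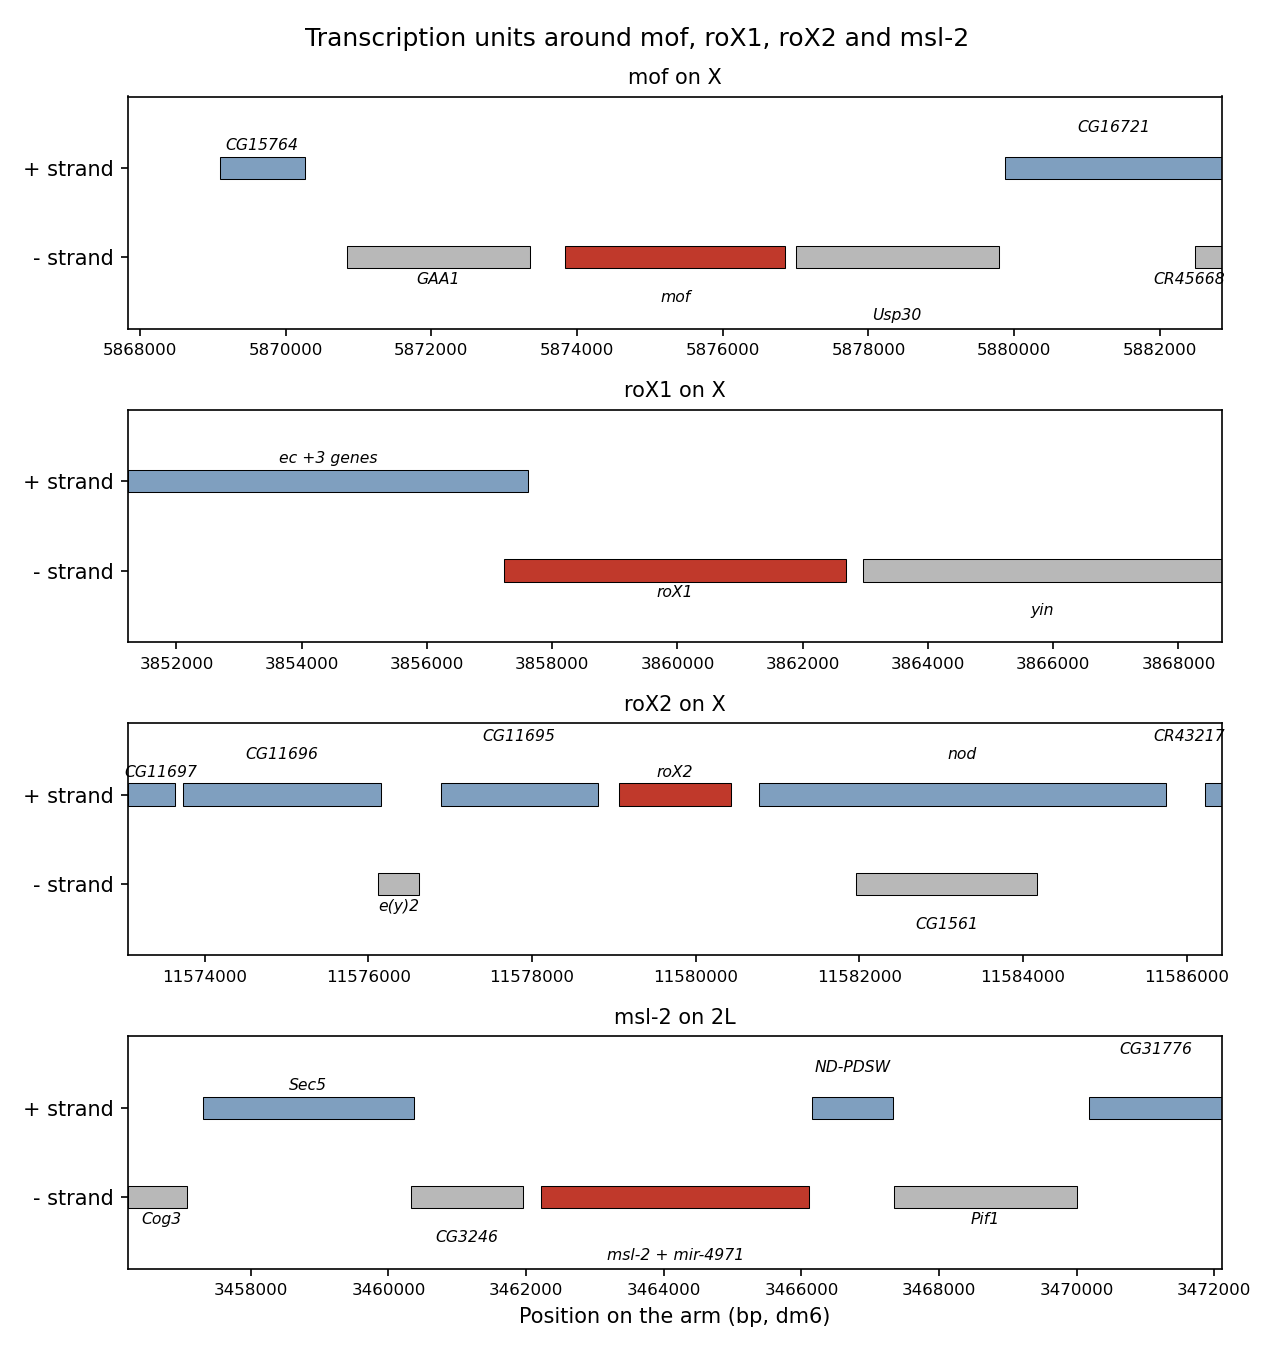
Maps of the TUs around mof, roX1, roX2 and msl-2, drawn to scale with 6 kb on either side; the x axis is the position on the arm in bp (dm6), the upper bars are plus-strand TUs, the lower bars minus-strand TUs, and the red bar is the named TU. roX1 is overlapped by the end of the ec TU, while mof and roX2 have no TU on the opposite strand within their bounds.

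TUs of the X were longer than those of the autosomes. The median X TU measured 2242 bp (interquartile range 1060.5 to 5453.5, n = 2399 TUs) against 1767 bp (882 to 4021, n = 13340) on the autosome arms, a difference of 475 bp. Each autosome arm had a shorter median than the X, from 1624 bp on 2L through 1723 bp on 3L and 1781 bp on 2R to 1888.5 bp on 3R (mean of the 4 arms 1754 bp, SD 111). Among TUs with a protein-coding gene the medians were 2682 bp on the X and 2148 bp on the autosomes. The permutation test gave p = 1e-05, the smallest that 100000 resamples can give (two-sided, Benjamini-Hochberg adjusted p = 7.00e-05 over 7 comparisons). With arms as the unit, the X ranked 1 of 5, for which the smallest exact p is 0.2, so arms alone cannot pass 0.05.

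The 3 longest TUs of the X merged many genes, and the 3 longest of the autosome arms held 1 protein-coding gene each. These few TUs do not show a difference in merging in general. TUs of several genes made up 7.34% of the X and 7.20% of the autosomes (Fisher's exact p = 0.830). On the X the longest was that of kirre, a cell adhesion gene of myoblast fusion, at 394149 bp (2740384 to 3134532, plus strand). It held 13 protein-coding genes and overlapped opposite-strand TUs that held 11 genes, w and rst among them. A TU of 291517 bp (12043698 to 12335214, plus strand) held Ten-a, a teneurin, with 7 other genes listed from CR43960 on, and a TU of 239347 bp (7166451 to 7405797, minus strand) held CR44357, unc-119, Atg5 and 5 other genes. The longest on the autosome arms were Myo81F with CR12798 at 1965857 bp (3R, 567076 to 2532932, plus strand), Pzl with CR45220 at 709421 bp (3R, 2554162 to 3263582, minus strand) and CG45782 with CR40450 at 434041 bp (3L, 25236940 to 25670980, minus strand).

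**Figure D2:**
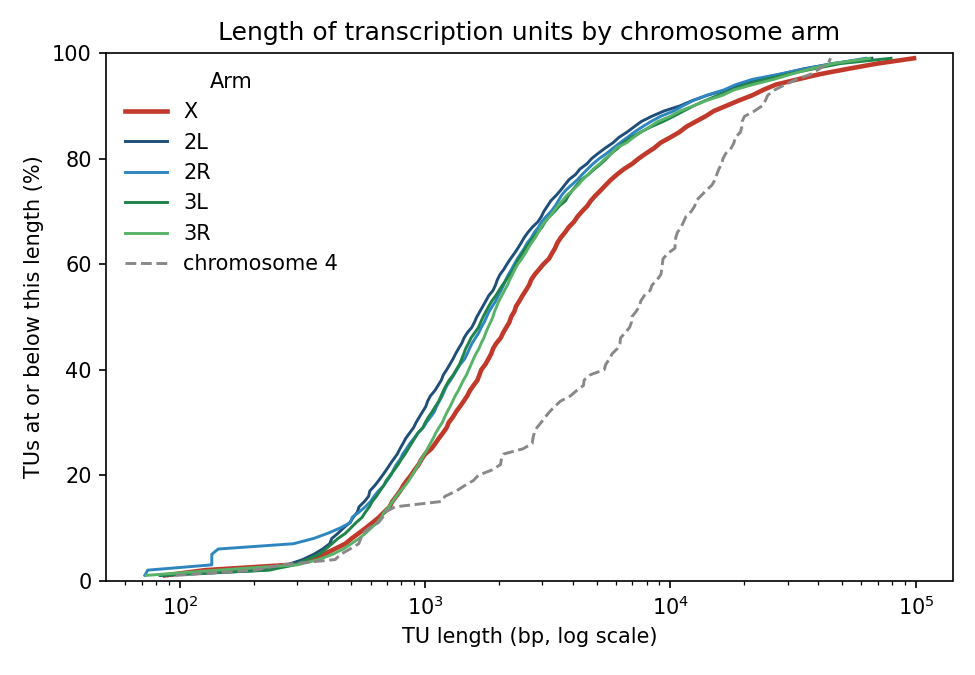
Cumulative distribution of TU length for the X, the 4 autosome arms and chromosome 4; the x axis is length in bp on a log scale and the y axis the percent of TUs at or below it, from the 1st to the 99th percentile. The X curve lies to the right of the 4 autosome arms at the median, 2242 bp against 1624 to 1888.5 bp, and chromosome 4 lies further right, with a median of 6955 bp.

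The X also carried fewer TUs per length. Counted up to the end of the last TU, the X had 103 TUs per Mb, against 111 on 3L, 119 on 3R, 128 on 2R and 135 on 2L. Its 2399 TUs held 2671 genes, and the 4 autosome arms held 14765 genes in 13340 TUs. Among TUs of at least 1000 bp the X was no longer the sparsest arm, with 78.3 per Mb against 77.9 on 3L and 90.0 to 90.9 on the other arms. These densities are counts without a test.

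Divergent starts, in which a TU on the opposite strand starts head to head within 500 bp upstream, were less frequent on the X. They were found for 542 X TUs (22.6%) and 3327 autosome TUs (24.9%), an odds ratio of 0.878 (95% confidence interval 0.792 to 0.974; Fisher's exact test, two-sided, p = 0.0144, adjusted p = 0.0336). Both TUs of a head-to-head pair are counted, so this p and interval overstate the certainty. The 4 autosome arms ranged from 23.8% on 2R to 25.8% on 2L. The call was lost when the X label was permuted over blocks of 1 Mb in place of single TUs (permutation p = 0.221), at distances of 250 bp (11.7% against 12.9%, exact p = 0.0899) and 1000 bp (32.5% against 33.5%, exact p = 0.335), and among TUs of at least 1000 bp (26.0% against 27.0%, exact p = 0.436).

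The distance to the nearest TU on either strand and the share of TUs with an opposite-strand overlap of at least 1 bp did not pass the test between the X and the autosomes. The median gap to the nearest TU was 72 bp on the X and 69 bp on the autosomes (permutation p = 0.783, adjusted p = 0.830), and autosome arms ranged from 51.5 bp on 2R to 81 bp on 3L. On the same strand alone the gap was wider on the X, 1252 bp against 1001 bp (permutation p = 1e-05, the smallest possible). A TU on the opposite strand overlapped 926 X TUs (38.6%) and 5271 autosome TUs (39.5%; odds ratio 0.962, 95% confidence interval 0.880 to 1.05, Fisher's exact p = 0.401, adjusted p = 0.562). When the overlap had to cover at least 50% of the shorter TU, the X had the higher share, 23.3% against 21.4% (exact p = 0.0496). No TU overlapped another on the same strand, on any arm, so that comparison has no test.

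Isolated TUs, of at least 2 kb and with no other TU within 500 bp of either end, numbered 233 on the X (9.71%) and 1199 on the autosomes (8.99%; odds ratio 1.09, 95% confidence interval 0.940 to 1.26, Fisher's exact p = 0.263, adjusted p = 0.461). At 250 bp the X share was higher, 17.1% against 14.8% (exact p = 0.00363), and at 1000 bp it was 5.25% against 5.58% (exact p = 0.560). TUs that merged several genes made up 7.34% of the X (176 TUs) and 7.20% of the autosomes (961 TUs; Fisher's exact p = 0.830, adjusted p = 0.830).

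TUs with no protein-coding gene were less frequent on the X, 379 TUs (15.8%) against 2426 (18.2%) on the autosomes (odds ratio 0.844, 95% confidence interval 0.750 to 0.950, Fisher's exact p = 0.00493, adjusted p = 0.0173). The share was 21.0% on 2L and 15.5% on 3R, so the X lay inside the range of the autosome arms. The call was lost without 2L (exact p = 0.0798), among TUs of at least 1000 bp (exact p = 0.0528) and with 1 Mb blocks permuted (permutation p = 0.255).

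**Figure D3:**
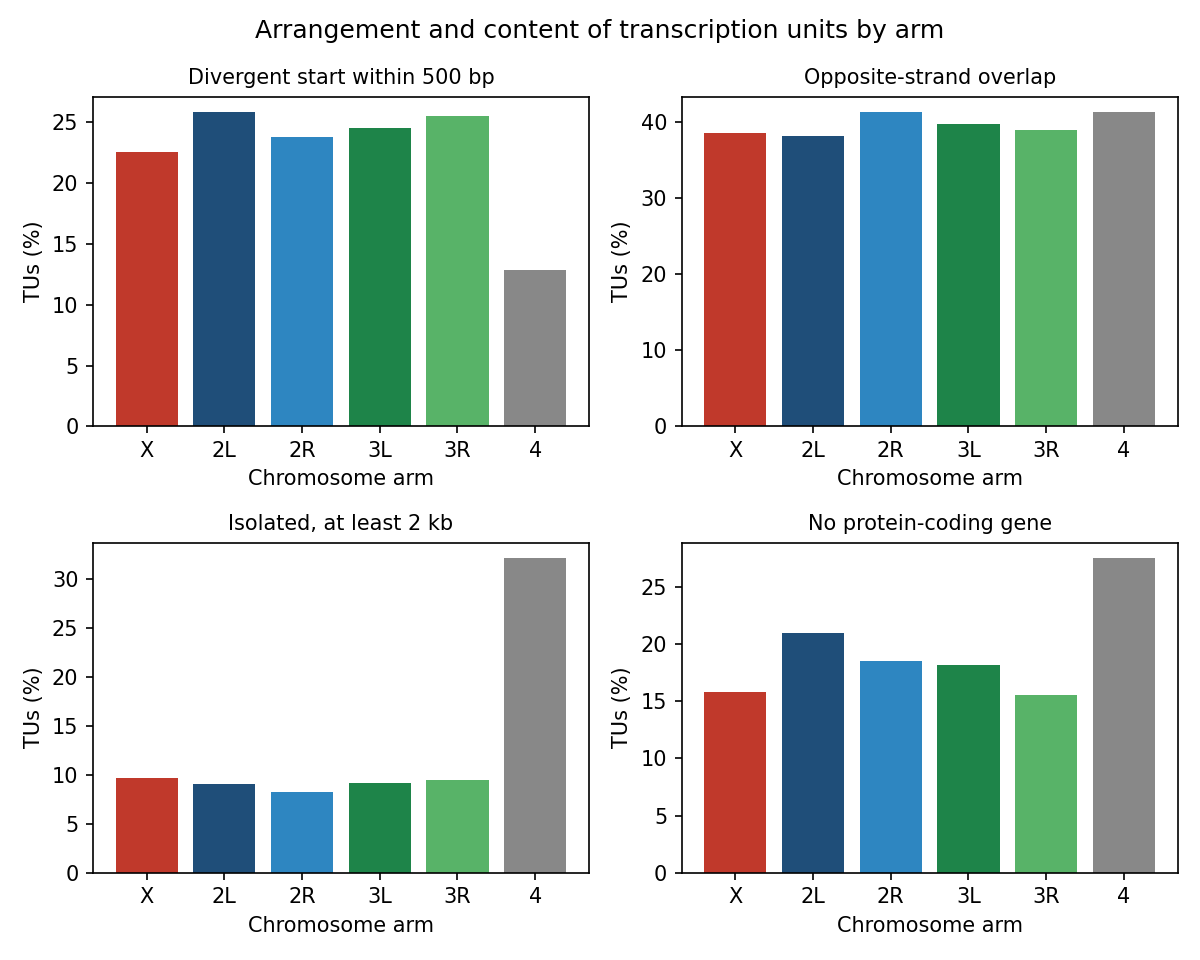
Percent of TUs with a divergent start within 500 bp, with opposite-strand overlap, isolated with at least 2 kb, or without a protein-coding gene, on each arm; bars start at 0 and the x axis gives the chromosome arm. The X has the lowest divergent share of the 5 large arms, 22.6%, and chromosome 4 has the highest isolated share, 32.1%.

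The gene lists showed which genes close to the subject of the study had near neighbours. Genes of Pol II pausing and elongation had divergent starts in 9 of 13 cases (69.2%), against 27.3% of the other TUs with a protein-coding gene (Fisher's exact p = 0.00196, adjusted p = 0.0269 over 55 list tests). The 4 NELF genes, whose products hold Pol II near the promoter, were all among them: Nelf-A on 3R faced CG3337 at 120 bp, NELF-B on the X faced CG12155 at 394 bp, TH1 on the X faced mei-41 at 260 bp, and Nelf-E on 3L faced RpL14 at 127 bp. Their TUs measured 5809, 2366, 2619 and 1438 bp. Each of the 13 genes had a divergent start or an opposite-strand overlap, and 9 had the overlap (exact p = 0.0439, adjusted p = 0.268). The share of the other TUs with either feature is not given, so the count for either feature has no reference. Within 250 bp, 38.5% of the list had a divergent start, 24.5 points above the other TUs, which no longer passed (exact test, adjusted p = 0.206).

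Pol II subunit genes had a median TU of 950 bp against 2230.5 bp for the other TUs with a protein-coding gene, which did not pass the test (permutation p = 0.139, adjusted p = 0.552). A divergent start was found for 7 of 12 (58.3%, Fisher's exact p = 0.0232, adjusted p = 0.160). RpII215, the largest subunit, which bears the CTD, spanned 7527 bp on the X and faced CG11699 at 295 bp. RpII140 (3R, 4321 bp) faced 140up at 243 bp, and RpII33 (2L, 970 bp) faced DNApol-gamma35 and GatC at 232 bp. Rpb4 shared a TU of 2645 bp on 3R with the histone acetyltransferase adaptor Ada2a, so reads of these genes fall in the same interval. CTD kinases and phosphatases had divergent starts in 4 of 11 cases (exact p = 0.505, adjusted p = 0.899). Cdk7, the serine 5 kinase of TFIIH, spanned 1519 bp on the X and faced snf at 259 bp, and its partners CycH (3L, 1313 bp) and Mat1 (2R, 1213 bp) and the Mediator kinase Cdk8 (3L, 1591 bp) had none.

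The NSL complex, in which MOF also acts, in both sexes, had 3 of 6 members with a divergent start (exact p = 0.355, adjusted p = 0.849). Rcd1 (2R, 4861 bp) faced pea at 30 bp and Rcd5 (3L, 2069 bp) faced CG11593 at 47 bp, while nsl1 (3R, 8321 bp) and dgt1 (3R, 2797 bp) had none. The third was wds on the X, 281 bp from CG13760, named after its values were seen.

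Hox genes, which pattern the body axis, formed the most isolated list. Of 8 TUs, 6 were isolated (75%) against 10.4% of the other TUs with a protein-coding gene (Fisher's exact p = 2.95e-05, adjusted p = 0.00110). Divergent starts numbered 0, which did not pass (exact p = 0.117, adjusted p = 0.552) and which isolated TUs cannot have within 500 bp. Long TUs were isolated more often in general, and among the 100 coding TUs nearest in length to each Hox TU the share was 32.4%. Their median length was 30563 bp against 2226.5 bp (permutation p = 4.00e-05, adjusted p = 0.00110). lab (17164 bp), pb (34264 bp) and Dfd (10593 bp) on 3R were isolated, and Scr (26862 bp) was overlapped by the TU or TUs of CR45901, CR45904 and CR45905. Antp was the other Hox gene without isolation, named after its values were seen. These 8 genes lie in 2 clusters on 3R and are not independent of each other.

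Embryonic cell type markers were also long, with a median of 13302 bp against 2226 bp (permutation p = 0.000140, adjusted p = 0.00257), and 0 of 14 had a divergent start (exact p = 0.0156, adjusted p = 0.125). The neuronal markers elav (X, 13992 bp), nSyb (3L, 7405 bp) and brp (2R, 37801 bp) and the glial marker repo (3R, 3411 bp) belonged to this list, and elav was overlapped by arg and repo by CG7156. X-linked reference genes had a median of 7557 bp (permutation p = 0.00978, adjusted p = 0.108). Of these, y (4737 bp) was overlapped on the opposite strand by the TU or TUs of 4 genes. The w TU (5868 bp) lay inside the kirre TU on the opposite strand, while N (37352 bp) and ct (69712 bp) had no overlap.

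Sex determination genes shared TUs with other genes in 3 of 7 cases (42.9% against 8.38%, Fisher's exact p = 0.0160, adjusted p = 0.125). Sxl, the switch gene that blocks msl-2 translation in females, spanned 23504 bp on the X from 7074550 to 7098053, minus strand, with mir-4956 inside its TU, and was isolated. tra (3L, 992 bp) was overlapped by l(3)73Ah, tra2 (2R, 2334 bp) held scaRNA:PsiU5-44 and was overlapped by Blos1, and dsx (3R, 43086 bp) was overlapped by lds. her, with mir-2497, was the other shared TU, named after its values were seen.

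Heat shock genes, long used to study paused Pol II, had a median TU of 2237 bp (permutation p = 0.993, adjusted p = 1). Hsp22 on 3L shared with CG4456 a TU of 2243 bp whose start faced Hsp67Bc at 225 bp. Hsp23 (884 bp) and Hsp26 (1010 bp), on the same arm, had neither an overlap nor a divergent start, and Hsp27 (1632 bp) was overlapped by CR43483. Among autosomal reference genes, RpL32 (3R, 933 bp), Gapdh1 (2R, 1480 bp) and eEF1alpha1 (2R, 4628 bp) had divergent starts at 309, 245 and 156 bp, and alphaTub84B (3R, 2241 bp) had none, its nearest facing start being at 516 bp (3 of 5 genes, exact p = 0.129, adjusted p = 0.552).

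Some genes share their interval with a neighbour in these TUs. Of 15991 TUs, 1144 (7.15%) merged several genes, 2851 genes in all, and 655 TUs merged several protein-coding genes. In this way 1488 of 13879 protein-coding genes (10.7%) shared a TU with another protein-coding gene. Such TUs made up 4.63% of the X and 4.06% of the autosomes (111 and 542 TUs, Fisher's exact p = 0.201). Among the genes of the lists, those in such TUs were Rpb4 with Ada2a, Hsp22 with CG4456, Su(Tpl) with the chromatin remodeller Mi-2, bin3 with tomboy40, and vas with solo, of which Su(Tpl), bin3 and vas were named after their values were seen.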

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

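The 1 Mb block, protein-coding, several-gene, non-coding and list tests were chosen after the data were seen, as was the bar on any overlap for isolated TUs. Over the comparisons of the X with the autosomes, 51 alternative values kept their direction and side of the threshold. Length kept both under each alternative run, from 438 bp longer without 2L to 634 bp with TUs of at least 1000 bp. Where a call changed, the cause was not tested. Values are X minus autosomes, in percentage points unless given in bp. The divergent share differed by -0.911 with TUs of at least 1000 bp, by -2.35 with 1 Mb blocks (permutation p = 0.221), by -1.27 at 250 bp and by -1.04 at 1000 bp. The non-coding share differed by -1.51 without 2L, by -1.26 with TUs of at least 1000 bp and by -2.39 with 1 Mb blocks (permutation p = 0.255). The direction turned for 4 results: the gap was -2 bp without 2R, several-gene TUs differed by -0.244 with TUs of at least 1000 bp, isolated TUs by -0.325 at 1000 bp, and overlap of at least 50% by 1.81, which newly passed (exact p = 0.0496). Differences that newly passed in the same direction were the same-strand gap, 251 bp, and isolated TUs at 250 bp, 2.34. The isolated share is not corrected for the longer TUs of the X. With TUs of at least 1000 bp the densities were 78.3 per Mb on X, 90.9 on 2L, 90.6 on 2R, 77.9 on 3L and 90.0 on 3R. All 5 densities, which have no test, moved by more than 10.6 per Mb, the SD of the 4 autosome arms.

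Of the list results, 146 alternative values kept direction and call. Pausing genes lost their divergent call at 250 bp (24.5). Sex determination genes passed for length with TUs of at least 1000 bp (20638.5 bp) and X-linked reference genes against all TUs (5731 bp). Directions turned, with no call on either side, as follows. Divergent starts: MSL 0.418 against all TUs and 13.4 at 1000 bp; heat shock 0.418, 13.4 and, with TUs of at least 1000 bp, 0.725. Overlap of at least 50%: Pol II subunits -19.2, sex determination -19.2, Hox 5.79, cell type markers 9.37, heat shock -19.2. TUs of at least 1000 bp: overlap of Pol II subunits -41.5 and of sex determination genes -1.45, several genes for Pol II subunits 10.05, length of heat shock genes -625.5 bp. Several genes for Pol II subunits were 1.11 against all TUs, and isolated autosomal reference genes 2.39 at 250 bp.

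No paired analysis was possible because the results come from the annotation and from no test on samples. Keeping 1 TU per gene changes nothing, since each gene is in 1 TU. Same-strand overlap is 0 under each setting. Arm lengths as denominator, and the GC content, GA repeat and core promoter motif results with their alternatives, were not run, since they need the genome sequence. Depth limits none of these values, which rest on no reads.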

Other observations

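The tests in this part were chosen after the data were seen. Chromosome 4, a small and largely heterochromatic autosome, differed from the large arms most clearly in TU length. Its 109 TUs had a median of 6955 bp against 1767 bp on the 4 autosome arms (permutation p = 1e-05, the smallest possible, adjusted p = 3.00e-05 over 6 tests). Isolated TUs made up 32.1% against 8.99% (Fisher's exact p = 1.60e-11, adjusted p = 9.62e-11), and divergent starts 12.8% against 24.9% (exact p = 0.00254, adjusted p = 0.00507). An isolated TU needs at least 2000 bp, so the isolated share is not corrected for the longer TUs of chromosome 4. Nor can an isolated TU have a divergent start within 500 bp, so these 2 shares are not separate results. Opposite-strand overlap was 41.3% and 39.5% (exact p = 0.695). These tests take TUs as independent, although chromosome 4 is a single stretch of 1.27 Mb. Against 75 autosome windows of that length with at least 20 TUs, 0 had a median as long (one-sided exact rank p = 0.0132), 3 had as high an isolated share (p = 0.0526, exact) and 5 as low a divergent share (p = 0.0789, exact), so the latter 2 did not pass. Windows with fewer TUs were left out, so these ranks do not cover autosome stretches that hold few TUs. The Y had 112 TUs, of which 79.5% held no protein-coding gene, and a median gap of 1692 bp to the nearest TU.

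Some gene classes were spread unevenly. Antisense RNA, snoRNA and snRNA genes did not pass (Fisher's exact test, adjusted p = 0.652, 0.209 and 0.243). tRNA genes made up 0.899% of X genes and 1.80% of autosome genes (24 and 266 genes, Fisher's exact p = 0.000390, adjusted p = 0.000877 over 9 classes), and lncRNA genes 8.72% and 11.2% (exact p = 0.000145, adjusted p = 0.000654). miRNA genes went the other way, 2.06% against 1.35% (55 and 199 genes, exact p = 0.00641, adjusted p = 0.00961), as did pseudogenes, with 53 genes on the X and 163 on the autosome arms (exact p = 0.000390, adjusted p = 0.000877). rRNA genes numbered 2 on the X and 96 on the autosome arms (exact p = 2.79e-05, adjusted p = 0.000251). The annotation lists no TU on unplaced sequence, so repeated genes that the assembly does not place on an arm are missing from these counts. Genes of these classes often lie in clusters, so single genes are not independent. Protein-coding genes made up 81.4% of X genes and 78.5% of autosome genes (exact p = 0.000801, adjusted p = 0.00144). None of these class tests was repeated without single arms or with 1 Mb blocks permuted. The share of TUs with no protein-coding gene lost its call without 2L and with such blocks. Of 258 snoRNA genes in the annotation, 14 (5.43%) had a TU of their own, against 28.1% of 256 miRNA genes and 86.1% of 13879 protein-coding genes. The TUs with the most genes were Arpc2 on 2L, with 17 snoRNA genes in 5971 bp, and the chromatin remodeller dom on 2R, with 15 in 18418 bp. RpS5a was the X TU with the most genes, 14 snoRNA genes beside the ribosomal protein gene in 4677 bp, and SLO2 on 2R held 15 protein-coding genes in 94802 bp.

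The longer TUs of the X were weighed against 3 properties of the annotation. Fewer short non-coding TUs do not account for all of the length difference, since X TUs with a protein-coding gene were still 534 bp longer by the median. Nor does merging account for all of it, since protein-coding TUs of 1 gene were 439 bp longer (permutation p = 1e-05 for both, the smallest possible). A part played by merging is not excluded. Neither test permuted 1 Mb blocks. X TUs had more annotated transcripts, 2.48 per TU against 2.12, and within strata of transcript number the mean log2 length difference was 0.16, against 0.36 without strata (permutation p = 1e-04, the smallest that 10000 resamples can give). The number of transcripts may thus account for part of the difference and not for all of it. No biological explanation was tested.

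Whether fewer divergent starts on the X follow from local spacing stays open. X TUs had a median of 13 other TUs within 50 kb, against 17 on the autosomes. Compared within 5 classes of that number, the X share was 1.06 percentage points higher on average (permutation p = 0.241). It was lower in 3 of the 5 classes, with -6.83 points in class 5, the densest, and 7.26 points in class 2, and without class 2 the average was -0.926 (permutation p = 0.368). The sign thus rests on class 2. On average no lower X share passed within classes, with or without class 2, which is what spacing predicts. A smaller difference of the X is not excluded. Regional variation along the arms stays open as well, since the permutation of 1 Mb blocks gave p = 0.221.

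Isolation of Hox TUs was weighed against their length. Among the 100 coding TUs nearest in length to each Hox TU, 32.4% were isolated on average, against 75% of the 8 Hox TUs. Sets matched in this way held as many isolated TUs in a share of 0.0152 of 100000 draws. Those draws take TUs singly, while the Hox genes lie in clusters of 5 and 3. Runs of 5 and 3 neighbouring coding TUs, each at least as long as the shortest Hox TU (10593 bp), held as many isolated TUs in a share of 0.0350 of 100000 draws. Hox TUs were thus isolated more often than single coding TUs of like length. The runs had only a minimum length, 10593 bp, while the median Hox TU measured 30563 bp, so they were not matched for length. Whether length and the likeness of neighbouring TUs together account for the isolation therefore stays open. Both shares lie under 0.05, but neither was adjusted for the choice of the Hox list as the most isolated of the lists tested. The list was fixed before the data were examined, but its isolation was tested after it had been seen, and no biological explanation was tested.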
